A study of Mus musculus with 4 samples.

How the data were processed

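Single-nucleus RNA was measured in the primary motor cortex of C57BL/6N mice, in 4 libraries of 1 library per group: ad lib sleep, sleep deprivation, and local administration of an adeno-associated virus (AAV) that expresses FLAG-tagged SIK3 under the human synapsin promoter, either wild-type SIK3 or SIK3 without exon 13. Per the labels, nuclei were taken up in a 10x Chromium 3' (v3.1) kit. The deposited values are whole-number UMI counts per gene and nucleus, made by the authors with Cell Ranger 6.1.2 on mm10 per the submitters' processing notes. They carry no normalization and no cell type annotation. The feature table pairs gene identifiers with symbols and holds a vector feature, WPRE_pA, which covers the end of the vector transcript by its name. Coordinates are 1-based on mm10, from the GENCODE vM21 annotation matched by gene identifier.

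The choices of comparisons, gene lists, cell type markers, the rule for named genes and most other settings tried were made before the data were examined. The thresholds that turn the marker lists into names, the treatment of doublets, and the split of nuclei by vector UMIs were set after the data were seen. Nuclei with at least 500.0 detected genes and under 5% mitochondrial UMIs were kept. Doublet scores came from Scrublet as built into scanpy. Its automatic threshold called 1, 0, 1 and 4 nuclei in the ad lib, sleep deprivation, wild-type AAV and exon 13 deleted AAV libraries, too few to have worked. The highest-scoring share that loading predicts, 0.8% per 1000 barcodes, was therefore called instead, with ties at the lowest called score included. The predicted shares were 7.55%, 4.76%, 5.58% and 5.01%, and 717 of 9390, 334 of 5811, 396 of 6948 and 318 of 6226 scored nuclei were called.

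Counts per nucleus were scaled to 10000, logged, and reduced to 2000 variable genes that were found in at least 20 nuclei. Genes of the lists, the vector feature, mitochondrial, X-inactivation and Y-linked genes took no part. Values were centred within each library and reduced to 30 principal components. Leiden clustering at resolution 1 on shared neighbours (15 per nucleus) gave the clusters. A marker counted as detected in a cluster at 0.25 of its highest cluster level. A cluster took the name of the non-excitatory class with at least 0.5 of its markers detected, or of excitatory neurons at 0.7. It stayed unnamed with markers of several classes, fewer than 3 detected markers, leading genes of another class, or low UMI counts and no marker among its leading genes. Class names stand for clusters that resemble the type by these markers ("excitatory neuron-like" and so on). Excitatory subclasses followed the same kind of rule, with a marker detected at 0.5 of its highest level. A cluster that drew too large a share of its nuclei from a single library got no subclass name, whatever its markers. This applied to cluster 27, with 78.8% from its largest library.

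Counts were summed over the nuclei of a class in each library and expressed as CPM, counts scaled to a class total of 1e6. Levels carry exact Poisson 95% intervals, fold ratios exact conditional 95% intervals, and shares of nuclei exact Clopper-Pearson 95% intervals. All of these cover counting error alone. With 1 library per group no difference between groups can be tested, so no p-value or count of changed genes is given. For each of 27 gene lists (571 genes), the median of log2 (CPM + 1) ratios was taken over members with a mean of at least 5 CPM, with an interval from 500 Poisson draws. Its percentile among 10000 random lists matched on mean expression in 20 bins describes these libraries and is no test. The lists were rapid immediate early genes, delayed activity-regulated genes, MAPK feedback genes, cAMP and CREB target genes, the SIK, LKB1, class IIa HDAC and CRTC pathway, core clock and clock output genes, sleep loss genes reported as higher and as lower, endoplasmic reticulum chaperones with the unfolded protein response, cytosolic heat shock proteins, glucocorticoid response, glutamatergic postsynapse, presynaptic vesicle release, voltage-gated potassium channels, voltage-gated calcium, sodium and HCN channels, GABA-A receptor subunits with the inhibitory postsynapse, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, interferon response, reactive astrocyte genes, microglial activation genes, microglial homeostatic genes, myelin genes, p53 and DNA damage response, long nuclear noncoding RNAs, mitochondrially encoded transcripts, and cytosolic ribosomal proteins. The lists were written from general knowledge and some share members.

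The rule for named genes took Sik3, the 10 highest and 10 lowest log2 ratios in excitatory neurons (mean of at least 20 CPM and at least 100 UMIs), and the 3 highest and 3 lowest in each other class with at least 100 nuclei in both libraries (mean of at least 50 CPM and at least 100 UMIs). It also took, of each list in the class discussed, the 3 members of highest mean CPM and the 3 measured members with the largest absolute log2 ratio. Mitochondrial, X-inactivation and Y-linked genes and markers of other broad classes were left out of the ranked genes. Genes named outside this rule are said to be so.

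The calculations were tested on simulated Poisson class sums with 200 genes changed by 2-fold or 0.5-fold. This checks the calculations and leaves out the spread between nuclei and between animals. For sleep deprivation against ad lib sleep in excitatory neurons (12005 genes), 95.2% of intervals covered the true ratio and all changed genes (100%) took the right direction. For the AAV comparison this was 95.3% and 100% in excitatory neurons (12022 genes), and 96.8% and 94% in microglia (13168 genes).

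Alternatives planned were clustering without library centring, nuclei thinned to 1500 UMIs, doublets kept, a strict filter (1000 genes, 1% mitochondrial) and a loose one (200 genes, 10% mitochondrial), list floors of 20 CPM or none, pseudocounts of 0.1 and 5, TMM factors from edgeR 4.0.16 in R 4.3.3, the mean over nuclei in place of summed counts, and totals without mitochondrial genes and Malat1. Added after the data were seen were the AAV comparison without cluster 27 or with vector-free nuclei alone, other vector UMI thresholds, microglia without nuclei that hold a macrophage-marker UMI, and list members chosen by the floor in vector-free nuclei (vector-rich lists) or in the libraries without vector (microglia), or with no floor. Thinning left out nuclei with under 1500 UMIs, which kept 3700 of 3724, 1852 of 1860, 2735 of 2748 and 2119 of 2131 excitatory nuclei in the order above. Losses were larger and less even in shallower classes. The median depth was 1444 UMIs in ad lib and 2397.5 in sleep deprivation microglia, and 1674 and 2977 UMIs in oligodendrocytes. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.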

Results

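Nuclei from the primary motor cortex of mice were profiled in 4 libraries: 1 after ad lib sleep, 1 after sleep deprivation, 1 after local AAV delivery of wild-type SIK3 and 1 after AAV delivery of SIK3 without exon 13. SIK3 is a salt-inducible kinase, and both vectors drive it in neurons. The libraries held 54070503, 49422196, 47662932 and 43655557 UMIs in this order, in 9438, 5944, 6978 and 6259 barcodes, of which 8225, 5270, 6336 and 5502 were kept as nuclei. Excitatory neurons were the largest named class, with 3724, 1860, 2748 and 2131 nuclei. Their share was 45.3% (95% interval 44.2 to 46.4) of kept nuclei after ad lib sleep and 35.3% (34.0 to 36.6) after sleep deprivation. Nuclei that no class could name made up 12.4%, 32.1%, 16.04% and 15.8%, and the median UMI count of excitatory nuclei was 7393, 13890, 9139 and 9967. The sleep deprivation library thus held more nuclei of very low depth and deeper named nuclei, a gap that can set shares of nuclei. The groups have no replicates, so every difference below is one between libraries with no replicate check, and all intervals cover counting error alone.

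Sik3 (ENSMUSG00000034135, chromosome 9, 46012820 to 46224194, plus strand) was measured in all 4 libraries, at 147 CPM (143 to 151) after ad lib sleep, 174 CPM (169 to 179) after sleep deprivation, 193 CPM (188 to 198) with the wild-type vector and 193 CPM (188 to 199) with the exon 13 deleted vector in excitatory neurons. The ratio of the AAV libraries was 1.0007 (0.962 to 1.04), and that of sleep deprivation to ad lib sleep was 1.19 (1.14 to 1.24). Reads from a 3' kit need not cover exon 13 or come from the vector, so this level checks neither the deletion nor the dose. The vector feature WPRE_pA had 0 UMIs in excitatory neurons of the ad lib and sleep deprivation libraries, where the floor of 3 counts was 0.0972 and 0.105 CPM. It reached 48.9 CPM (46.3 to 51.5) in the wild-type and 128 CPM (123 to 132) in the exon 13 deleted library, 2.62-fold higher (2.46 to 2.79). Few nuclei carry this difference: 23 wild-type nuclei with 10 or more vector UMIs held 506 of 1409 UMIs and 53 exon 13 deleted nuclei 2330 of 3072, and the level in all other excitatory nuclei was 31.7 CPM in both libraries. At least 1 vector UMI was seen in 20.8% (19.3 to 22.4) and 25.7% (23.9 to 27.6) of excitatory nuclei. Astrocytes, which the synapsin promoter should leave silent, still had 18.1% and 17.7% at a lower median depth of 2791 and 2915 UMIs, so a single vector UMI is close to background. At least 3 vector UMIs were seen in 3.38% and 4.65% of excitatory nuclei, against 0.704% and 0.804% of astrocytes, 1.22% and 2.53% of oligodendrocytes (median depth 1964 and 2095 UMIs) and 2.66% and 5.74% of unnamed nuclei. Per UMI of the class, its level was also higher in oligodendrocytes (165 and 146 CPM) than in excitatory neurons. The vector feature was thus found in the libraries labelled AAV alone, but not in neurons alone. At least 1 vector UMI was seen in 17.5% and 21.0% of oligodendrocytes, and free RNA was not told apart from expression in glia.

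After sleep deprivation, excitatory neurons had lower levels of cholesterol synthesis genes and higher levels of postsynaptic and heat shock genes than after ad lib sleep. All 19 measured cholesterol synthesis genes were lower, with a median log2 ratio of -0.42 (-0.46 to -0.33) and a percentile of 0 among random lists. The wild-type AAV library was also below ad lib sleep (-0.16, -0.20 to -0.08, 2 of 19 higher), and sleep deprivation was below the wild-type AAV library (-0.24, -0.30 to -0.18, 1 of 19 higher). The size of the difference thus depends on the reference library. The wild-type AAV library also differs from ad lib sleep by surgery, virus and SIK3, so whether the ad lib library stands apart cannot be told. Postsynaptic genes were at 0.10 (33 of 43) for the wild-type AAV library minus ad lib sleep and 0.03 (28 of 43) for sleep deprivation minus the wild-type AAV library. Heat shock genes were at 0.10 (9 of 15) and 0.11 (10 of 15). The AMPA receptor subunit Gria1 was 1.52-fold higher (1.49 to 1.54) and the glucocorticoid-induced chaperone Fkbp5 2.60-fold higher (2.36 to 2.88). The median over all genes with a mean of at least 5 CPM was -0.03, so these shifts are not a shift of scale.

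The gene with the highest ratio among 6949 ranked was Gm5820 (chromosome 18, 38892458 to 38971276), 3.68-fold higher (3.21 to 4.23), followed by the fibroblast growth factor Fgf1 (ENSMUSG00000036585, chromosome 18, 38838673 to 38929472) at 188 against 59.0 CPM (3.19-fold, 3.02 to 3.36). These genes overlap on opposite strands, and no label says how the counting used strand, so reads could be split between them. Nearby 9630014M24Rik (chromosome 18, 38601534 to 38789045) was at 88.1 against 29.3 CPM. The others of the 10 highest were Serinc2, Fkbp5, Gm12536, Crispld1, Nectin1, Rhbdl3 and Gm10848, with ratios of 2.03 to 2.62. Gm20752 was lowest, at 7.59 against 32.6 CPM (0.233-fold, 0.200 to 0.270), and Rad51ap2, Pamr1, Gm45904, Abi3bp, Fam205c, Hunk, Sst, 2900076A07Rik and Gm13684 followed at ratios of 0.368 to 0.458. Sst marks an interneuron type and its UMIs in excitatory nuclei can be free RNA.

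Among activity-regulated groups in excitatory neurons, 6 of 17 rapid immediate early genes were higher after sleep deprivation, with a median of -0.26 (-0.35 to -0.14) at percentile 0.15. Members went both ways: Arc was 1.90-fold higher (1.73 to 2.09) and Egr3 1.74-fold higher (1.56 to 1.94), while Btg2 was at 6.86 against 20.3 CPM. The median turned to 0.06 when only the 7 members above 20 CPM were used, 5 of them higher, and was 0.002 after thinning, so the group's direction rests on low genes. Delayed activity-regulated genes had a median of -0.02 (10 of 22 higher), although Sorcs3 was at 425 against 260 CPM and the activity-induced scaffold Homer1 at 349 against 286 CPM. MAPK feedback genes had a median of 0.09 (6 of 10), with Spred2 and Spred3 1.42-fold and 1.81-fold higher, cAMP and CREB target genes 0.00 (9 of 18), and the SIK, LKB1, class IIa HDAC and CRTC pathway -0.02 (10 of 24). Core clock and clock output genes had a median of 0.07 (11 of 19), with Per2 at 22.4 against 13.5 CPM and Ciart at 6.26 against 12.2 CPM. Of the genes listed beforehand as reported higher after sleep loss, 18 of 25 were higher (0.17, 0.12 to 0.28, percentile 100), and of those reported lower, 4 of 12 were higher (-0.22, -0.27 to -0.14, percentile 0.69).

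Stress-related groups went in several directions. Cytosolic heat shock proteins were higher in 14 of 15 cases (0.19, 0.16 to 0.26, percentile 99.9), with the chaperone Hsp90ab1 at 330 against 243 CPM and Hsph1 1.48-fold higher. Endoplasmic reticulum chaperones with the unfolded protein response had a median of 0.08 (0.04 to 0.16, 13 of 21 higher, percentile 97.3), or 0.20 with a floor of 20 CPM. Pdia3 and Pdia4, protein disulfide isomerases, were at 50.2 against 35.3 and 10.04 against 6.70 CPM, while Dnajb9 was at 9.48 against 14.5 CPM. Glucocorticoid response genes had a median of 0.16 (0.00 to 0.34, 7 of 11; 0.28 after thinning). The p53 and DNA damage list had a median of -0.09 (2 of 9), interferon response -0.29 (3 of 8, -0.06 after thinning) and nuclear-encoded oxidative phosphorylation -0.02 (16 of 35).

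Synaptic and channel genes leaned higher in excitatory neurons of the sleep-deprived library. For the glutamatergic postsynapse, 30 of 43 members were higher (0.15, 0.12 to 0.18, percentile 100), Shank1 at 191 against 123 CPM and Cacng2 at 138 against 92.4 CPM among them. Presynaptic vesicle release had a median of 0.08 (25 of 39, Cplx2 at 111 against 74.0 CPM). Voltage-gated calcium, sodium and HCN channels had a median of 0.10 (17 of 26), with the calcium channel subunit Cacna2d3 at 989 against 631 CPM. Voltage-gated potassium channels had 0.05 (18 of 31), a median that was -0.02 after thinning, and GABA-A receptor subunits with the inhibitory postsynapse -0.01 (7 of 16). Genes of other cell types and quality markers moved as well: microglial homeostatic genes had a median of -0.36 (2 of 7, P2ry12 at 69.1 against 88.7 CPM), microglial activation genes -0.26 (1 of 6), reactive astrocyte genes -0.08 (2 of 4) and myelin genes -0.03 (5 of 10). Mitochondrially encoded transcripts had 0.34 (0.21 to 0.36, 9 of 13), cytosolic ribosomal proteins 0.03 (22 of 34; -0.01 when clustered without library centring) and long nuclear noncoding RNAs 0.04 (6 of 10).

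**Figure D1:**
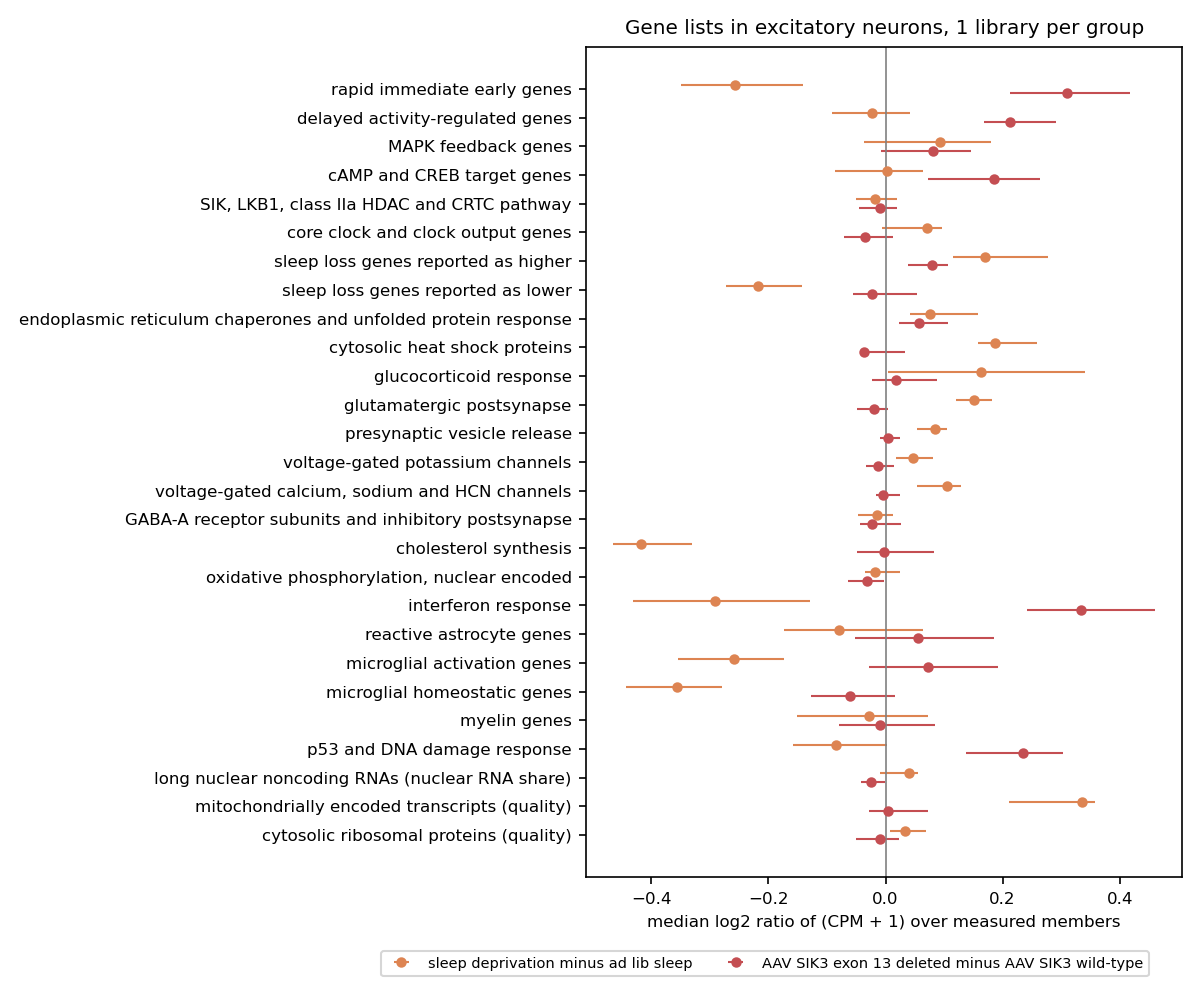
Median log2 (CPM + 1) ratio of each of the 27 gene lists in excitatory neurons, for sleep deprivation minus ad lib sleep and for exon 13 deleted minus wild-type AAV; points are medians and bars are 95% intervals for counting error alone. Cholesterol synthesis lies at -0.42 in the first comparison, and rapid immediate early genes lie at -0.26 in the first and 0.31 in the second.

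Glia of the sleep deprivation library had higher levels of glucocorticoid-responsive genes. In oligodendrocytes 16 of 17 measured members were higher, with a median of 1.42 (0.97 to 1.72, percentile 100). Fkbp5 was at 141 against 11.9 CPM (11.9-fold, 7.10 to 21.3), the transcription factor Zbtb16 at 348 against 46.7 CPM (7.46-fold, 5.71 to 9.89) and the kinase Sgk1 at 309 against 48.2 CPM (6.41-fold, 4.91 to 8.48). Plin4, a lipid droplet protein, was 49.5-fold higher on 2 counts in the ad lib library (13.3 to 415). The same list had medians of 0.98 (0.77 to 1.22, 16 of 18) in astrocytes, 0.54 (14 of 17) in endothelial cells, 0.38 (12 of 13; 0.15 after thinning) in inhibitory neurons, 0.32 (-0.13 to 0.84, 8 of 14; 0.86 after thinning) in oligodendrocyte precursors, 0.13 (7 of 11) in striatal projection neurons and 0.64 (0.26 to 1.21, 12 of 15) in microglia, of which the sleep deprivation library held 88 nuclei. The microglial median was -0.005 when clustered without library centring. The wild-type AAV library also lay above ad lib sleep in oligodendrocytes, with all 17 measured members higher and a median of 1.12 (0.75 to 1.41), and both of these comparisons use the single ad lib library. Fkbp5 was at 103 CPM in both AAV libraries and Zbtb16 at 307 and 414 CPM. Without the ad lib library, sleep deprivation minus the wild-type AAV library gave 0.24 (0.10 to 0.37, 14 of 17) in oligodendrocytes and 0.49 (0.29 to 0.62, 17 of 18) in astrocytes.

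**Figure D2:**
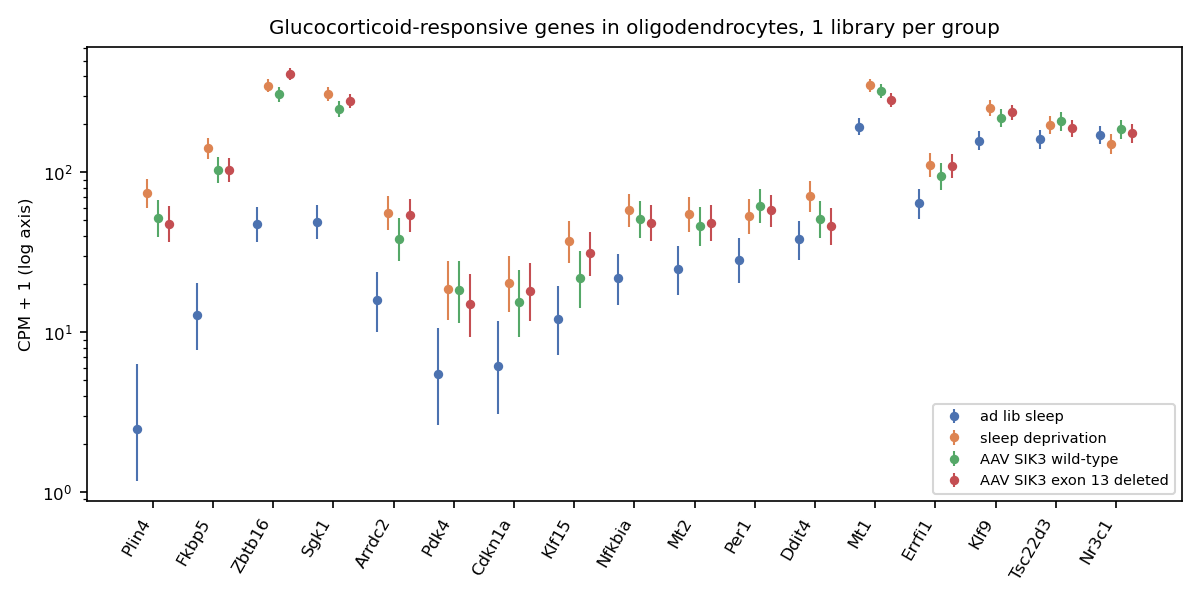
Level in CPM + 1 (log axis) of 17 glucocorticoid response genes in oligodendrocytes of the 4 libraries; points are levels and bars exact Poisson 95% intervals for counting error alone. Fkbp5 is at 11.9 CPM after ad lib sleep and at 141 CPM after sleep deprivation, and the other libraries also lie above ad lib sleep for most genes.

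Other classes showed part of the neuronal pattern. Cholesterol synthesis genes were lower in inhibitory neurons (-0.38, -0.47 to -0.25, 2 of 19 higher), astrocytes (-0.49, -0.54 to -0.17, 4 of 21; -0.28 with the strict filter) and striatal projection neurons (-0.46, 1 of 18), but not clearly so in oligodendrocytes (-0.06, -0.23 to 0.11, 9 of 21), where cholesterol feeds myelin, or in endothelial cells (10 of 20 higher). Heat shock genes had medians of 0.26 (12 of 15) in inhibitory neurons and 0.36 (16 of 18) in oligodendrocytes. In astrocytes Slc24a4, a cation exchanger, was 19.3-fold higher (9.90 to 43.1). It was at 5.82 CPM after ad lib sleep and at 50.1 and 60.3 CPM in the AAV libraries. Phyhd1 was 4.74-fold higher, while D030055H07Rik, Frem1 and Phf21b were lowest at ratios of 0.174 to 0.388. In oligodendrocytes Gm20713 was at 129 against 16.3 CPM, and Sytl2, Agk and Adamts2 were lowest. Endothelial cells had Zbtb16 at 471 against 91.8 CPM (366 and 460 CPM in the AAV libraries) and also Ccnd3 and Pglyrp1 highest, with the cell cycle inhibitor Cdkn1a at 87.0 against 11.7 CPM, and Grip1, Npas3 and Sox2ot lowest. Inhibitory neurons had Tafa1 at 119 against 46.7 CPM, Gm5820 and Il1rapl2 highest and Gm28153, 4930590L20Rik and Gm15680 lowest. Striatal projection neurons had Maml3 at 421 against 118 CPM, Gm13052 and Bcl2 highest and Gulp1, Gm15952 and Gm15680 lowest, in a class whose median over all genes was -0.12.

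With the exon 13 deleted vector, excitatory neurons had higher levels of rapid immediate early, delayed activity-regulated, cAMP-responsive and interferon-responsive genes than with the wild-type vector. All 17 measured immediate early genes were higher (median 0.31, 0.21 to 0.42, percentile 100), among them the activity-induced transcription factors Egr1 at 61.4 against 43.0 CPM and Npas4 at 19.8 against 11.2 CPM (1.77-fold, 1.53 to 2.05). The neurotrophin Bdnf (ENSMUSG00000048482, chromosome 2, 109674700 to 109727007) was at 50.2 against 24.0 CPM (2.10-fold, 1.91 to 2.31), and the synaptic pentraxin Nptx2 at 28.4 against 8.05 CPM (3.52-fold, 3.03 to 4.11). Cholesterol synthesis, lower after sleep deprivation, had a median of 0.00 here (9 of 19 higher). The median over all genes was 0.04. Against ad lib sleep, which both differences share, the immediate early median was -0.21 (3 of 16 higher) for the wild-type and 0.09 (12 of 18) for the exon 13 deleted vector. The immediate early median was 0.14 with a floor of 20 CPM and 0.48 after thinning.

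Delayed activity-regulated genes had a median of 0.21 (0.17 to 0.29, 15 of 20, percentile 100), with Scg2 1.70-fold and Sorcs3 1.38-fold higher and Homer1 0.942-fold. For cAMP and CREB targets it was 0.18 (0.07 to 0.26, 13 of 17; 0.03 with a floor of 20 CPM), and for interferon response 0.33 (0.24 to 0.46, 7 of 7, percentile 99.9), with Rnf213 at 17.9 against 9.64 CPM. The p53 and DNA damage list had 0.23 (0.14 to 0.30, 10 of 10, Psrc1 at 14.0 against 8.29 CPM and Mdm2 at 40.1 against 32.9 CPM), but 0.10 without cluster 27 and -0.01 in nuclei with 0 vector UMIs. Endoplasmic reticulum and unfolded protein response genes had 0.06 (0.02 to 0.11, 15 of 21, percentile 74.7), or -0.01 with TMM factors, and Ddit3, a stress-induced transcription factor, was at 10.4 against 5.96 CPM. Sleep loss genes reported as higher had 0.08 (16 of 24), those reported as lower -0.02 (5 of 12), core clock genes -0.04 (7 of 18, Per3 at 80.5 against 58.4 CPM), MAPK feedback genes 0.08 (6 of 10), the SIK pathway list -0.01 (11 of 24), heat shock proteins -0.04 (7 of 15) and glucocorticoid response 0.02 (6 of 12).

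The synaptic lists showed little difference between the AAV libraries in excitatory neurons. Medians were -0.02 for the postsynapse (20 of 43), 0.00 for vesicle release (20 of 39), -0.01 for potassium channels (14 of 31, Kcna1 at 130 against 101 CPM), 0.00 for calcium, sodium and HCN channels (13 of 27) and -0.02 for GABA-A receptor subunits (7 of 16). Oxidative phosphorylation had -0.03 (14 of 35, Cox8a at 223 against 273 CPM). Genes of other cell types and quality markers had medians of 0.06 for reactive astrocytes (2 of 4), 0.07 for microglial activation (4 of 6), -0.06 for microglial homeostasis (3 of 7), -0.01 for myelin (5 of 10), -0.02 for long nuclear RNAs (3 of 10), 0.00 for mitochondrial transcripts (8 of 13) and -0.01 for ribosomal proteins (17 of 34). The highest ratios among 6960 genes were, besides WPRE_pA and Bdnf, those of Gm32647 at 30.4 against 11.3 CPM, AC149090.1 at 416 against 207 CPM, Gm19951, Lama2, Fbn1, Krt20, Gm49906 and Strip2. AC149090.1 was also 1.80-fold to 2.33-fold higher in inhibitory neurons, astrocytes, oligodendrocytes and striatal projection neurons, so it differs between the libraries as a whole. C77080 was lowest at 16.5 against 28.7 CPM, followed by Shoc1, Gm16105, Gm49171, Grik1, Rmst, Grin3a, Hrh3, Palmd and Dynlt1f at ratios of 0.648 to 0.759.

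The AAV difference in these groups was larger in excitatory nuclei with at least 3 vector UMIs than in nuclei with 0. There were 93 such nuclei with the wild-type and 99 with the exon 13 deleted vector, and both the split and the genes named for it were chosen after the data were seen. Bdnf was there at 334 against 18.6 CPM (18.0-fold, 11.6 to 29.4), Scg2 at 232 against 30.9 CPM, Npas4 at 71.5 against 5.30 CPM, Nptx2 at 163 against 4.42 CPM and Ddit3 at 57.0 against 9.72 CPM. The stress-induced transcription factor Atf3 was at 106 CPM against a single count (119-fold, 21.1 to 4758), while Fos was at 4.26 against 7.95 CPM and Arc at 12.8 against 26.5 CPM. Sik3 was at 484 against 376 CPM (1.29-fold, 1.13 to 1.46), compared with 180 and 183 CPM in vector-free nuclei. Its ratio was 1.07 (0.879 to 1.31) with 3 to 9 and 1.12 (0.940 to 1.35) with 10 or more vector UMIs. As lists, p53 and DNA damage genes had a median of 1.94 (1.77 to 2.46, 15 of 15), interferon response 1.78 (22 of 22), delayed activity genes 1.39 (19 of 25; 0.91 without cluster 27), immediate early genes 0.95 (0.58 to 1.18, 17 of 22) and the postsynapse -0.50 (-0.58 to -0.42, 11 of 44). Some of these members pass the floor of 5 CPM only because they are high in the exon 13 deleted nuclei. With members chosen by that floor in vector-free nuclei the medians were 1.85 (10 of 10), 1.14 (7 of 7), 1.16 (14 of 20), 0.61 (11 of 16) and -0.50 (10 of 43). Quality and other lists differed too: long nuclear noncoding RNAs had -0.71 (2 of 10 higher, percentile 0.03), mitochondrial transcripts -0.33 (2 of 13), core clock genes -0.37 (4 of 19) and calcium, sodium and HCN channels -0.36 (11 of 27). The cAMP and CREB targets had 0.89 (13 of 20). Of lists for other cell types, reactive astrocyte genes had 0.66 (5 of 6) and microglial activation genes 0.59 (5 of 8). Microglial homeostatic genes had 0.10 (4 of 8) and myelin genes -0.05 (4 of 11). The olfactory receptor genes Olfr115 and Olfr112 were at 226 and 160 CPM against 0 counts, at least 85.1-fold and 60.4-fold higher against the floor of 3 counts. Vector-rich nuclei were not matched in kind or vector load: the sums of vector UMIs were 846 and 2550, and 43 of the 99 nuclei lay in cluster 27, which took 89 of its 113 nuclei from this library and may be that library, not a type. Named subclasses differed too, in the order wild-type and exon 13 deleted: 22 and 3 nuclei of L2/3 IT, 22 and 4 of L4/5 IT, 26 and 21 of L6 CT, and 13 and 22 of L6 IT. The list medians of vector-rich nuclei, higher or lower, were not compared within subclasses. In vector-free nuclei the medians were 0.27 (16 of 16) for immediate early, 0.16 (16 of 20) for delayed activity and 0.25 (7 of 7) for interferon genes. Vector-free means 0 vector UMIs detected, and such nuclei need not lack the vector. Of them, 23 of 1583 with the exon 13 deleted and 7 of 2176 with the wild-type vector lay in cluster 27.

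**Figure D3:**
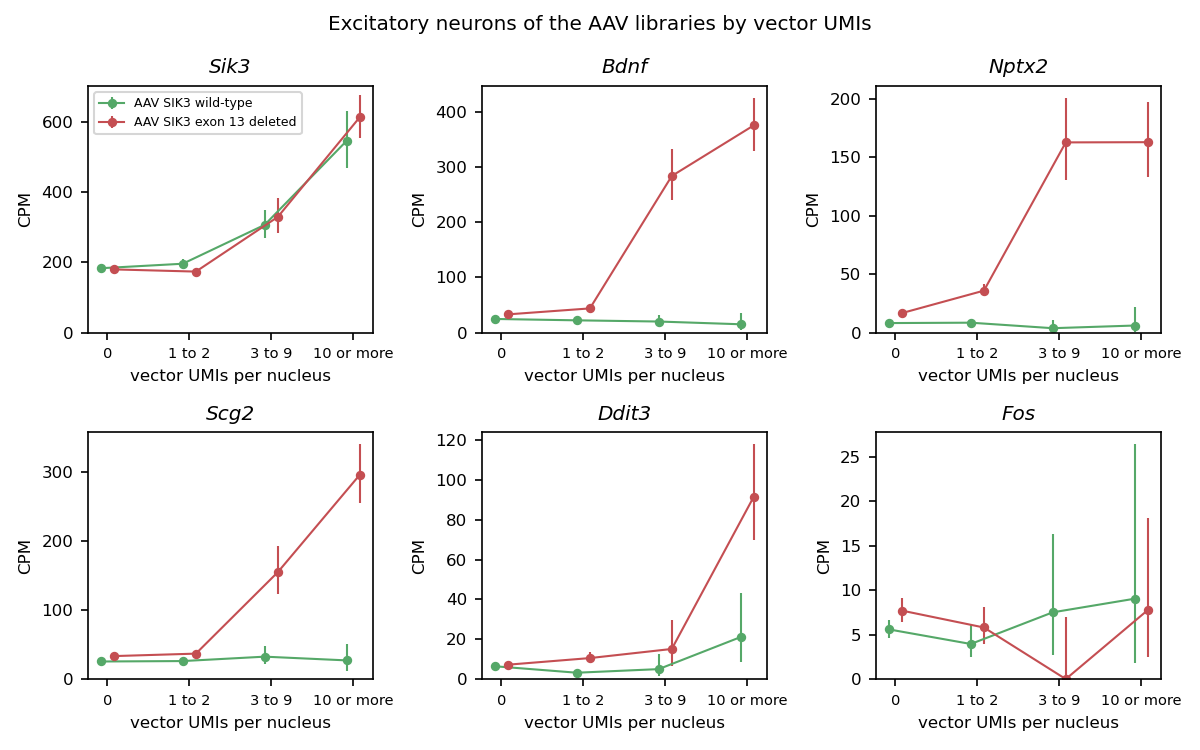
Level in CPM of Sik3, Bdnf, Nptx2, Scg2, Ddit3 and Fos in excitatory nuclei of the 2 AAV libraries by number of vector UMIs (0, 1 to 2, 3 to 9, 10 or more); points are levels and bars exact Poisson 95% intervals for counting error alone. Bdnf is at 33.0 CPM with the exon 13 deleted and 24.7 CPM with the wild-type vector in nuclei with 0 vector UMIs, and at 375 against 15.1 CPM with 10 or more, while Sik3 is at 612 against 545 CPM there and Fos shows no such gap.

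Glia also differed between the AAV libraries. In microglia (218 and 213 nuclei) interferon response genes were higher with the exon 13 deleted vector in 26 of 28 cases (median 1.20, 0.94 to 1.55, percentile 100), with the antigen-presenting molecule H2-K1 at 228 against 53.02 CPM (4.30-fold, 2.74 to 7.01). Microglial activation genes had a median of 1.47 (0.80 to 2.33, 20 of 21), or 0.61 with a floor of 20 CPM and 0.60 (12 of 13) with members measured in the libraries without vector, with Ctsd at 482 against 316 CPM and Cd74 at 101 CPM against 0 counts (floor 6.63 CPM). Microglial homeostatic genes had -0.14 (-0.19 to 0.02, 6 of 14). All 7 measured markers of macrophages and monocytes, which are named outside the rule, were higher in the same cluster. The largest ratios were those of Cd163, at 61.4 against 6.63 CPM, and F13a1, at 136 against 22.1 CPM. Mrc1 was at 202 against 124 CPM and Stab1 at 151 against 137 CPM. The neuronal genes Lingo2, Lrrtm4 and Gria4 were lowest. Interferon medians were 0.95 (17 of 18) in oligodendrocyte precursors, 0.62 (16 of 18, and 0.31 after thinning) in astrocytes, 0.49 (15 of 15) in oligodendrocytes, 0.19 (18 of 30) in endothelial cells, 0.16 (7 of 9) in inhibitory neurons and -0.06 (2 of 6) in striatal projection neurons. Members of these and of the reactive astrocyte lists were chosen by the floor of 5 CPM in the same AAV libraries, which favours genes high in either one. Members measured in the libraries without vector were not tried in these classes. In oligodendrocyte precursors 3 counts were 5.99 CPM with the wild-type and 5.38 CPM with the exon 13 deleted vector, so members near the floor rest on few UMIs. Reactive astrocyte genes were higher in astrocytes (0.72, 0.19 to 1.04, 9 of 9), with the intermediate filament Gfap at 100 against 39.2 CPM (2.56-fold, 1.83 to 3.63), and in oligodendrocytes (0.57, 7 of 8), with complement C4b at 48.4 against 11.8 CPM. In inhibitory neurons Gm19951, Mir670hg and AC149090.1 were highest and Rps2, Fth1 and Chrna7 lowest.

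The 2 main comparisons shared no library, and their log2 ratios in excitatory neurons were close to unrelated across genes (Pearson r -0.028, Spearman rho -0.018 over 7015 genes, which are not independent replicates). Most excitatory nuclei of the AAV libraries had 0 vector UMIs (79.2% with the wild-type and 74.3% with the exon 13 deleted vector). These values therefore say little about vector-rich nuclei, for which no correlation was calculated. In 7 other classes r lay between -0.057 in oligodendrocytes and 0.058 in striatal projection neurons. Counting error pulls r toward 0, most in classes of low depth, and was not corrected for. The log2 ratios of the first and second comparison had standard deviations of 0.24 and 0.12 in excitatory neurons and 0.68 and 0.58 in microglia. In classes of low depth an r near 0 therefore cannot tell unrelated from noisy ratios. Immediate early genes had medians of -0.26 in the first, which was near 0 after thinning, and 0.31 in the second comparison, and cholesterol synthesis had a median below 0 in the first comparison and at 0.00 in the second.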

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

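The tests of unequal vector RNA, of uptake by another excitatory subclass, of nuclei mixed with another cell type, of an ad lib library that stands apart, of free neuronal RNA and of the AAV injection as such were chosen only after the result was seen. The vector feature WPRE_pA is a signal outside the main comparisons that lay above its level of 0 UMIs in the libraries without vector. It was at 48.9 CPM in excitatory neurons, 99.4 CPM in microglia and 165 CPM in oligodendrocytes of the wild-type AAV library, and at 128, 329 and 146 CPM in those of the exon 13 deleted AAV library. Single nuclei set some of these levels: 1 microglial nucleus held 98 of 150 vector UMIs (116 CPM without it), 1 wild-type oligodendrocyte 71 of 182 (102 CPM without it), and 53 exon 13 deleted excitatory nuclei 2330 of 3072.

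In vector-rich excitatory nuclei, 72 of 83 measured members of the p53, interferon, delayed activity and immediate early lists were higher with the exon 13 deleted than with the wild-type vector (median log2 ratio 1.57, 1.38 to 1.79), but the floor of 5 CPM favours members high in these nuclei, and on the 53 members that pass it in vector-free nuclei, a choice made after the result was seen, the median was 1.10 (0.87 to 1.26, 42 above 0). Their level lay above the highest named excitatory subclass of the other 3 libraries. The median was 0.926 (0.75 to 1.02), 0.489 (0.33 to 0.58) on the 53 members and 0.56 (0.29 to 0.62) on these members in nuclei outside cluster 27. This argues against uptake by another named subclass, but a rarer type or state within a subclass is not covered. In cluster 27 their level lay above its 24 nuclei in those libraries (0.817, 0.52 to 1.22, on the 53 members). Those 24 nuclei held 184446 UMIs, against 533751 in the vector-rich nuclei of cluster 27. Members near the floor of 5 CPM rest on very few counts there, so this comparison cannot decide. Against the wild-type AAV level plus the share of each other class that its markers give, the median was 1.53 (1.31 to 1.60; 1.05, 0.86 to 1.12, on the 53 members), which argues against nuclei mixed with another cell type, but this test replaced 2 earlier forms after their values were seen: one on the 10 highest genes alone, and one against the highest class or subclass level, which gave -0.83 (-0.89 to -0.66, 22 of 83 above 0) and did not exclude mixing, and was replaced on the ground that microglia and endothelial cells set the highest level of interferon genes. The intervals against the highest subclass, the highest class or subclass and the wild-type level plus other classes cover counting error of the exon 13 deleted nuclei alone. They leave out that of the reference. With 3 to 9 vector UMIs the vector level was 416 CPM with the exon 13 deleted and 425 CPM with the wild-type vector. The median there was 0.910 (0.73 to 1.22) on the 67 members measured in that bin. It was 1.04 (0.69 to 1.28) on the 83 members and 0.680 (0.45 to 0.96) on the 53 members. This argues against unequal vector RNA as the whole cause. The bound of 0 took the place, after the value was seen, of a higher one that the interval holds. These nuclei were not matched in kind: 22 of 46 exon 13 deleted nuclei lay in cluster 27, against 0 of 70 wild-type nuclei. L2/3 IT held 3 of the exon 13 deleted and 16 of the wild-type nuclei, and L4/5 IT held 3 and 13. What remains at equal vector level can thus reflect the kind of nucleus. How much unequal vector RNA adds stays open, and the deletion itself stays untested as a biological cause with 1 library per vector.

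Glucocorticoid-responsive genes were higher in oligodendrocytes of the sleep deprivation library. The median was 1.55 after thinning. Thinning keeps the expected share of each gene within a nucleus and changes only the weight of nuclei, so it cannot decide on depth as a cause. Oligodendrocytes of the sleep deprivation library lay 2.47 above excitatory neurons in the same genes, which argues against free neuronal RNA. An ad lib library that stands apart remains a candidate explanation: the wild-type AAV library was also 1.12 above it. The wild-type AAV library differs from the ad lib library by surgery, virus and SIK3 as well, so this value cannot tell these apart. Without the ad lib library, sleep deprivation minus the wild-type AAV library gave 0.24 (0.10 to 0.37, 14 of 17 higher), and sleep deprivation itself stays open as a cause with 1 library per group.

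Interferon and microglial activation genes were higher in microglia of the exon 13 deleted AAV library, although with members measured in the libraries without vector the medians were 1.10 (20 of 21) and 0.60 (12 of 13). The interferon median of the wild-type AAV library over ad lib sleep was 0.104 (-0.20 to 0.60), but the injection as such cannot be told apart, since 1 injected library per vector does not exclude a reaction that differs between animals. Border macrophages or monocytes in the cluster may contribute to the activation genes, since 7 of their markers had a median log2 ratio of 1.58 (0.70 to 2.46), at least that of the activation list. Single markers ranged from 0.14 for Stab1 to 3.03 for Cd163. A few extreme nuclei cannot be told apart, as the activation median without the top 10% of nuclei was 0.831 (0.48 to 1.31), with 196 and 192 nuclei kept. The deletion was not tested apart from the animal.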

How the results depend on the processing

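Alternatives added after the data were seen were those without cluster 27, by vector UMIs, without nuclei with macrophage-marker UMIs and with list members chosen in nuclei outside the contrast, and the others were planned. No paired analysis was possible because each group has 1 library. Of 656 alternative values for list medians of sleep deprivation minus ad lib sleep, 606 stayed within counting error, 45 moved beyond it and 5 turned direction, and of 798 for the AAV comparison 736, 59 and 3 did. For single genes 508 of 580 and 641 of 749 stayed within it, 72 and 107 moved and 0 and 1 turned. For vector-rich nuclei 250 of 296 list values stayed, 45 moved and 1 turned, and 183 of 224 gene values stayed and 41 moved. For shares of nuclei 101 of 144 stayed and 43 moved, for the Sik3 level 6 of 12 stayed and 6 moved, for wild-type AAV minus ad lib sleep 68 of 72 stayed and 4 moved, and for the correlation 10 of 14 stayed, 3 moved and 1 turned.

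For sleep deprivation minus ad lib sleep in excitatory neurons, thinning gave 0.0022 for immediate early genes, -0.021 for potassium channels and -0.31 for cholesterol synthesis. A floor of 20 CPM gave 0.062 for immediate early genes (fewer genes) and 0.20 for endoplasmic reticulum genes. The mean over nuclei gave -0.33 for cholesterol synthesis. Clustering without centring gave -0.015 for ribosomal proteins, and in microglia -0.0049 for glucocorticoid response. For the AAV comparison in excitatory neurons, TMM factors gave -0.0092 and thinning 0.12 for endoplasmic reticulum genes, the mean over nuclei 0.0037 for oxidative phosphorylation, and vector-free nuclei -0.014 for p53 genes. Immediate early genes had 0.48 after thinning, 0.14 with a floor of 20 CPM and 0.21 with a pseudocount of 5. In microglia the floor of 20 CPM gave 0.61 and members measured in the libraries without vector 0.60 for activation genes (fewer genes), and in endothelial cells the strict filter gave a log2 ratio of 1.13 for Cdh18. In vector-rich nuclei, 3 to 9 UMIs gave 0.065 for vesicle release and 1.32 for p53 genes, and 2 or more UMIs 1.45 for p53 genes. The correlation was 0.011 in vector-free nuclei, -0.0032 without cluster 27, -0.039 with the mean over nuclei and -0.070 with a floor of 50 CPM. Except where fewer genes or nuclei enter, the cause was not tested. Depth limits what microglia and oligodendrocyte precursors can show, since their sums in the sleep deprivation library were 227930 and 409637 UMIs, over 88 and 75 nuclei.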

Other observations

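Striatal projection neurons, which lie below the cortex, made up 3.65%, 4.61%, 3.42% and 7.58% of nuclei in the ad lib, sleep deprivation, wild-type AAV and exon 13 deleted AAV libraries. In this class rapid immediate early genes had a median log2 ratio of -1.05 (-1.53 to -0.94, 1 of 17 higher) for the wild-type AAV library minus ad lib sleep and 0.56 (0.22 to 0.75, 10 of 12) for the exon 13 deleted minus the wild-type AAV library. Their vector level was 22.0 and 24.8 CPM in the AAV libraries. In excitatory neurons the wild-type AAV library minus ad lib sleep gave -0.21 (3 of 16) for immediate early genes, -0.16 (2 of 19) for cholesterol synthesis and 0.26 (0.20 to 0.30, 15 of 18, percentile 100) for core clock and clock output genes, with Per2 at 36.8 against 13.5 CPM. The clock list was also higher there in inhibitory neurons (0.16, 17 of 18), astrocytes (0.27, 11 of 18), oligodendrocytes (0.47, 13 of 19) and microglia (0.35, 14 of 18). The hours of collection are not in the labels.

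The excitatory nuclei without a subclass name lay in cluster 27, with 11, 5, 8 and 89 nuclei in the 4 libraries. The name was withheld for the large share of a single library, not for its markers. The olfactory receptor genes Olfr111, Olfr112, Olfr113 and Olfr115, chosen after their values were seen, are found in layer 6b nuclei of the other libraries, with Olfr115 at 244 CPM after ad lib sleep, 93.8 CPM after sleep deprivation and 156 CPM with the wild-type vector, and Olfr113 at 68.4, 9.50 and 54.7 CPM. In vector-rich nuclei of the exon 13 deleted library Olfr115 was at 226 CPM, while 9 other markers of layer 6b had a median log2 ratio of -2.91 to layer 6b nuclei, such as Cplx3 at 1.70 against 106 CPM. In nuclei with 0 vector UMIs Olfr115 was at 17.3 CPM with the exon 13 deleted and 6.48 CPM with the wild-type vector.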
